A study of Drosophila melanogaster with 48 samples.

How the data were processed

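Testes of bam-/-;hsBam flies were grown at 22 °C, heat shocked as pupae for 30 min at 37 °C and kept at 25 °C afterwards, per the labels. Lysate libraries covered 0, 16, 24, 32, 48 and 72 h, and polysome gradient libraries the free, 40S, 60S, 80S, 2-3 ribosome and 4+ ribosome pools at 24, 48 and 72 h, with 2 libraries per group and 48 in all. Libraries were made with QuantSeq 3′ FWD and aligned with Bowtie 0.12.8 to dm6, per the submitters' processing notes. Each deposited file gives the read counts of cleavage sites for each stop codon, packed as pairs of position and count in a text column, so the unit of a cell is other than a plain count. The lowest deposited count is 20 in lysate and 10 in fraction files, and sites of a stop codon lie at least 51 nt apart, which fits the trimming and 50 nt merging that the names of the files state. How reads inside genes or from internal A-rich stretches were removed is not given in the sources used here.

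Pairs were unpacked in Python 3.11.15, and counts of a gene were summed over its stop codons. Entries that name several genes held at most 0.0428% of a library's reads and stayed out of tests. A gene or site missing from a library is called unlisted and entered the tests at 10 reads (lysate) or 5 (fractions), between 0 and the lowest listed count. FlyBase symbols matched for 10996 of 11029 genes in lysate and 11992 of 11997 in fractions. In lysate files 1394 of 5761 plus-strand keys (24.2%) and 1339 of 5811 minus-strand keys (23.0%) lay within 3 nt of the annotated dm6 stop codon, although the labels name dm6. These files were therefore treated as not in dm6 coordinates, and no other build was tried. In fraction files 6608 of 6610 plus-strand keys (99.97%) did, and 0 of 6049 minus-strand keys, which lay at the start codon. Sites were therefore joined between the 2 kinds by gene and distance from the stop codon, and dm6 positions are printed from fraction files alone. Of 6676 lysate pairs 6157 were found in fractions, 91.1% of the sites within 5 nt.

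Lysate libraries held 12.04 to 20.7 M listed reads and fraction libraries 0.445 to 9.57 M. Differences in level were tested with limma 3.58.1 in R 4.3.3 (voom, then robust moderated statistics), with scaling by trimmed means (factors 0.724 to 1.30 in lysate and 0.595 to 2.95 in fractions). All 12 lysate or all 36 fraction libraries shared the spread, and the 2 kinds were never tested together. The design had named edgeR, which was not used because the unit of the files is not a plain count; DESeq2 was not run for the same reason. Genes entered the tests of level if listed in both libraries of at least 1 group, and the tests of site choice with a mean of at least 10 reads at the pair. For site choice, sites of different libraries were joined within 50 nt, the pair of most used sites in lysate was taken for the stop codon with most reads of a gene and kept where each site held at least 5% of the pair's reads in a group, and log2(proximal/distal) was tested in limma with weights from the reads and a robust trend, in libraries with at least 60 (lysate) or 30 (fraction) reads at the pair, which is 3 listing minimums. The Benjamini-Hochberg adjusted p threshold was 0.05. The 23 gene lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01 where 3 or more members were measured, and again with an estimated correlation. They were tMAC, testis TAFs (tTAFs), spermatocyte and meiotic regulators, spermatid and sperm structural genes, Y-linked fertility genes, early germ cell genes, mitotic division, DNA replication, piRNA pathway, cleavage and polyadenylation machinery, proteins of the ELAV and related families, cytoplasmic ribosomal proteins, translation initiation factors, translational repressors and mRNP proteins, mitochondrial respiratory chain, heat shock genes, and markers of cyst cells, hub, accessory gland and ejaculatory duct, muscle, fat body and haemolymph, pigment and terminal epithelium, and neuron. Correlations with time used 100000 permutations of the libraries and comparisons of switch classes 10000 permutations across genes.

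In each comparison of levels, the rule set for named genes took bam first in lysate, then the 10 largest rises and falls (5 at 16, 24 and 32 h) past the threshold with mean log2 CPM of at least 4 and replicates that do not overlap, and list members. For sites it took the 12 largest rises and 8 largest falls (5 and 3 at 16, 24 and 32 h; 6 and 6 in fractions). Pairs of sites within 100 nt were passed over, an exception set after the files were seen. The report names part of these, and list members were picked after their values were seen, for known function. Some genes that met the rule or belong to a list are not reported here.

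The tests were tried on simulated reads with a spread taken from the replicates, with changes placed in well-covered genes only. All genes and libraries of a test shared a single spread, and few genes were changed. The real libraries differed in spread and composition, so the false calls below need not match those in these data. With 200 changed of 9775 genes, the lysate test at 72 h recovered 81.4% of changes of log2 1 and 100% of log2 2, with 8 false calls. Of 200 changed of 10133 genes, 4+ against free at 72 h recovered 14.3% and 80.4% with 6 false calls, and the change from 24 to 72 h 2.04% and 21.6% with 1. For sites, at log2 odds of 2 and 4, lysate at 72 h recovered 48.7% and 89.2% of 161 changed among 3582 genes (5 false), 4+ against free at 72 h 10.8% and 59.4% of 199 among 3897 (2 false), and fractions at 72 h against 24 h 92.5% and 98% of 180 among 2638 (6 false).

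Alternatives covered scaling, the fill for unlisted genes and sites, the mean read minimum (50), the joining distance (25 and 100 nt), a 2-fold or 20 percentage point minimum, the choice of sites, an F test over all sites, the pool set against 4+, the libraries that share the spread, limma-trend, a replicate block, fry for lists, and leaving out each library. Those on CG18628, on all 60S libraries, on listed genes, on fill values, on sites in the 3′ UTR or over 100 nt apart, on the F test and on limma-trend were chosen after seeing the data. Windows of poly(A) signals were not analysed here, as the genome sequence was not used here.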

Results

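RNA 3′ ends were counted in testes of bam-/-;hsBam flies, in which germ cells keep dividing as spermatogonia until a heat-shock copy of bam, a gene needed for the step from spermatogonium to spermatocyte, is switched on. Pupae were kept at 37 °C for 30 min, and testes were collected 0, 16, 24, 32, 48 and 72 h later. By the labels every library came from shocked animals. Hours after the pulse therefore also follow the age of the animal and recovery from the shock. Changes with time below cannot be told apart from these. Heat shock genes, by their median change, and bam stood lower at 0 h than at 16 h (below). The levels alone therefore do not show that the 0 h testes had been shocked. Total lysate gave 12 libraries, 2 per time. A polysome gradient gave 36 more, 2 for each of the free, 40S, 60S, 80S, 2-3 ribosome and 4+ ribosome pools at 24, 48 and 72 h. Lysate libraries held 12.04 to 20.7 M reads (median 15.7 M) at sites listed from 20 reads upward, in 7063 to 10041 genes. Fraction libraries held 0.445 to 9.57 M (median 5.53 M) at sites listed from 10 reads upward, in 1870 to 10006 genes. The lowest of these was replicate 2 of the 72 h 60S pool, and the next lowest held 2.65 M. A gene called unlisted below lay under those minimums, which does not exclude expression. Replicate libraries correlated at r = 0.847 (0 h) to 0.981 in lysate and at 0.346 (72 h 60S) to 0.972 in fractions. The labels name biological replicates but not separate crosses or dissections, so p-values measure the spread between 2 libraries per group, which may be technical. Of the chance orders of 2 against 2 libraries, 33.3% do not overlap.

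The reads of bam did not pass the test at any time, although both 16 h libraries lay above both 0 h libraries. Its level was 14.8 ± 0.695 scaled CPM (mean ± SD, n = 2 here and below) at 0 h and 80.8 ± 0.813 at 16 h, 79.9 ± 39.8 at 24 h, 57.4 ± 54.95 at 32 h, 19.9 ± 13.2 at 48 h and 28.3 ± 21.3 at 72 h. The log2 changes of bam against 0 h were 2.45, 2.33, 1.59, 0.37 and 0.66, with limma adjusted p of 0.328, 0.257, 0.351, 0.798 and 0.644 (Benjamini-Hochberg). Those at 48 h and 72 h turned to -0.48 and -0.16 without replicate 2 of that time. A 3′ tag of bam does not separate the heat-shock copy from the resident gene and does not check the deleted part.

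At 16 h, which asks what changed in the hours after the pulse, the calls included genes of fat body, haemocytes and muscle. The amylase gene Amy-p fell from 626 ± 30.1 to 24.9 ± 7.05 CPM (log2 -4.67, adjusted p = 2.01e-04). The prophenoloxidase genes PPO1 and PPO2 of haemocytes fell from 86.6 ± 14.98 to 1.302 ± 1.84 (-6.01) and from 149 ± 35.1 to 2.70 ± 1.01 (-5.80). Adh of fat body rose from 241 ± 195 to 1906 ± 151 (3.28, adjusted p = 0.0240). The myosin heavy chain gene Mhc rose from 65.4 ± 8.97 to 193 ± 9.20 (1.57, adjusted p = 0.0336) and the small heat shock gene Hsp23 from 221 ± 73.7 to 924 ± 9.68 (2.11, adjusted p = 0.0404). CG34434 was unlisted at 0 h and reached 11.1 ± 3.66 CPM. Genes changed in lysate at 16 h against 0 h numbered 92 of 10335 (48 higher, 44 lower) by limma with Benjamini-Hochberg adjustment. That count was 316 without 0 h replicate 1, 1780 without 0 h replicate 2, 47 without 16 h replicate 1 and 25 without 16 h replicate 2. The calls of Adh, Mhc, Hsp23 and PPO2 were lost without either 16 h library. Of the marker lists, muscle genes stood higher as a set (median log2 1.11, camera adjusted p = 1.81e-09, adjusted p = 0.422 with an estimated correlation), with 1 of 17 passing over all genes and 15 when adjusted over the list alone. Cyst cell markers (0.72; 0 of 15, or 2 over the list alone; 0.00952, 0.422 with an estimated correlation) and accessory gland markers (2.67, or 2.28 with unlisted values at their highest; 0 of 17; 0.0144, 0.791) were also higher as sets. Early germ cell genes were lower as a set (-0.43, but -0.01 with total counts; 0 of 23; 0.0465, 0.487 with an estimated correlation). Fat body and haemolymph genes had 2 higher and 2 lower of 15 (5 and 2 adjusted over the list alone; median 1.01; 0.0465, 0.580), and heat shock genes 2 higher of 16 (4 adjusted over the list alone; camera adjusted p = 1.45e-04, 0.487 with an estimated correlation). In a refit to genes listed in both libraries of 0 h or 16 h the fat body set did not pass (camera adjusted p = 0.116), while the other sets named here did. With only the libraries of the groups compared, 0 genes passed (1417 at an unadjusted p under 0.05 in the shared fit). Scaling by total counts gave 330 genes (88.2% higher) and moved the median of all genes from 0.00 to 0.44. Marker sums went from 1361 and 1848 to 2256 and 2504 CPM for muscle and from 798 and 1077 to 2802 in each library for fat body, but from 260 and 353 to 235 and 258 for hub and from 64.2 and 93.8 to 62.2 and 64.9 for pigment and terminal epithelium.

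At 24 h genes of the germ line were among those changed. The testis-specific nascent polypeptide gene betaNACtes1 was unlisted at 0 h and reached 37.2 ± 7.81 CPM (adjusted p = 2.25e-05). The RNA-binding protein gene Rbp4 rose from 4.68 ± 1.98 to 86.2 ± 0.932 (log2 4.26, adjusted p = 1.76e-04). The poly(A) polymerase gene Gld2 rose from 5.38 ± 0.336 to 138 ± 3.70 (4.67), fest from 0.859 ± 1.21 to 28.7 ± 0.321 (4.53) and kmg from 1.10 ± 1.55 to 18.4 ± 3.82 (3.75). The replication genes PCNA and Mcm7 fell from 2719 ± 1218 to 721 ± 13.1 (-1.84, adjusted p = 0.0183) and from 118 ± 54.2 to 21.1 ± 3.29 (-2.40, adjusted p = 0.0297), and CycE from 68.8 ± 15.2 to 13.9 ± 2.49 (-2.29). DNA replication genes were lower as a list, with a median below 0 under each scaling (-0.83; 8 lower of 28, and 12 lower with 1 higher adjusted over the list alone; camera adjusted p = 9.31e-08, 0.0140 with an estimated correlation). The tMAC list, which holds a spermatocyte transcription complex, had 1 of 8 members past the test, comr (4.28 ± 0.904 CPM, unlisted at 0 h), and a camera adjusted p of 0.00728 (0.235 with an estimated correlation; median 0.61, or 0.35 with unlisted values at their highest). Spermatocyte regulators had 3 higher of 13 (4 higher and 3 lower over the list alone, camera adjusted p = 0.587). Their mean was 0.60 and their median -0.40, but 0.07 with total counts. In a refit to genes listed in both libraries of 0 h or 24 h, the median of the 10 members was -0.22. That refit called 0 of 8 tMAC genes (camera adjusted p = 0.111). Of the sets below, cyst cell (0.0906) and fat body markers (0.230) did not pass there. Early germ cell, mitotic division, muscle and heat shock genes did, as did DNA replication genes. Early germ cell genes had 0 of 23, or 2 lower over the list alone (median -0.35, but 0.12 with total counts; 0.0357, 0.287 with an estimated correlation). Mitotic division genes had 1 lower of 38 (11 adjusted over the list alone; camera adjusted p = 4.82e-06, 0.235 with an estimated correlation) and muscle genes 0 of 17, or 6 higher over the list alone (0.87; 4.82e-06, 0.235). Heat shock genes were higher in 3 of 16, or 10 over the list alone (1.17; 9.31e-08, 0.235 with an estimated correlation), and fat body genes had 1 higher and 2 lower of 15 (0.90; 0.0479, 0.714). Of the cyst cell markers, higher as a set (0.82, or 0.57 with unlisted values at their highest; 0.0127, 0.235 with an estimated correlation), ImpL2 (2.11) and eya (1.83) rose, calls lost without either 24 h library. Genes changed in lysate at 24 h against 0 h numbered 166 by limma with Benjamini-Hochberg adjustment, 83 each way. Without 0 h replicate 1 or 2 the count was 324 or 2483, and without 24 h replicate 1 or 2 it was 23 or 21. PCNA, Mcm7, CycE and comr no longer passed in either of the latter, and kmg did not without 24 h replicate 2. With only the libraries of the groups compared, 0 passed. Scaling by total counts gave 501 genes (89.2% higher) and moved the median of all genes from -0.10 to 0.38. It turned the ribosomal protein median from -0.31 to 0.17.

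At 32 h fest and genes of the tMAC and testis TAF lists had risen. fest reached 242 ± 3.56 CPM (log2 7.60, adjusted p = 3.33e-06). The tMAC genes aly and achi rose from 26.6 ± 10.1 to 96.6 ± 14.2 (1.89, adjusted p = 0.00254) and from 12.1 ± 3.24 to 98.3 ± 4.53 (3.04). The testis TAF gene nht rose from 5.86 ± 2.44 to 61.8 ± 4.72 (3.45). betaNACtes1 (148 ± 11.5), CG10862 (189 ± 12.3) and the mitochondrial ATP synthase gene ATPsynbetaL (89.6 ± 25.6) were all unlisted at 0 h. The gap junction gene zpg of early germ cells fell from 47.8 ± 16.0 to 5.19 ± 0.806 (-3.17, adjusted p = 0.00288), stet from 17.2 ± 5.18 to 1.51 ± 2.14 (-3.47) and Mcm7 to 14.5 ± 7.92 (-3.005). RpLP2 of the large ribosomal subunit fell from 13737 ± 5789 to 5686 ± 218 (-1.21, adjusted p = 0.0415), a call lost without 0 h replicate 1, without either 32 h library and with total counts. As lists, tMAC genes rose in 7 of 8 (median 3.68, or 3.46 with unlisted values at their highest; camera adjusted p = 3.39e-09, 0.0332 with an estimated correlation) and testis TAFs in 4 of 4 (3.02, or 2.36; 2.98e-05, 0.0979 with an estimated correlation). The list of spermatocyte regulators had 4 higher and 2 lower of 13 (median 0.19, mean 1.39; 0.294). DNA replication genes were lower in 11 of 28 (-0.76; 1.46e-06, 0.0239 with an estimated correlation) and ribosomal protein genes in 29 of 90, or 56 adjusted over the list alone (-0.61, and -0.02 with total counts; 1.23e-11, 0.242 with an estimated correlation). Spermatid genes had 9 higher of 36, or 12 adjusted over the list alone (median 1.01, or 0.46 with unlisted values at their highest; 0.0189, 0.730 with an estimated correlation), early germ cell genes 4 lower of 23 (median -0.45, but 0.14 with total counts), and heat shock genes 6 higher of 16, Hsp68 among them (3.37 ± 4.77 to 231 ± 114 CPM). Genes changed in lysate at 32 h against 0 h numbered 1246 by limma with Benjamini-Hochberg adjustment (751 higher, 495 lower). This became 3335 without 0 h replicate 2, 423 without 32 h replicate 1 and 397 without 32 h replicate 2, and 2512 (94.2% higher; median of all genes 0.56) with total counts. With only the libraries of the groups compared 94 genes passed. The Hsp68 call was lost without any 1 of the 4 libraries.

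At 48 h most genes of spermatid structure were higher than at 0 h. The spermatid genes Mst77F (477 ± 2.03 CPM), Mst84Db (453 ± 31.6), dj (297 ± 15.7) and the testis tubulin gene betaTub85D (328 ± 41.2) were unlisted at 0 h, as were the testis TAF genes can and sa (the latter at 82.4 ± 6.15). fest stood at 322 ± 23.5 (log2 8.01, adjusted p = 1.44e-07) and aly at 251 ± 14.1 (3.27, adjusted p = 5.86e-06), while the leucyl aminopeptidase gene S-Lap2 rose from 1.29 ± 1.82 to 850 ± 86.5 (9.12). CG18628, which took 36.5% and 34.8% of all reads at 0 h and 8.69% to 19.9% in the later libraries, fell from 471437 ± 47061 to 91177 ± 34435 CPM (-2.43, adjusted p = 1.58e-04). zpg remained low (8.16 ± 0.358; -2.51), and RpLP2 fell further to 4080 ± 210 (-1.69). Spermatid genes were higher in 33 of 36 (median 6.80, or 6.07 with unlisted values at their highest; camera adjusted p = 3.56e-12, 0.196 with an estimated correlation). The tMAC list had 7 higher of 8 (4.56, or 4.11), testis TAFs 4 of 4 (5.003, or 4.56), and spermatocyte regulators 9 higher and 1 lower of 13. Ribosomal protein genes were lower in 66 of 90 and higher in 3 (-0.9996, and -0.29 with total counts; camera adjusted p = 4.78e-17, 0.185 with an estimated correlation), and DNA replication genes lower in 15 of 28 and higher in 2 (-1.06; 1.82e-05, 0.0399 with an estimated correlation). Genes changed in lysate at 48 h against 0 h numbered 4753 by limma with Benjamini-Hochberg adjustment (3324 higher, 1429 lower; 69.9% higher). Total counts gave 5502 (93.0% higher) and moved the median of all genes from 0.43 to 1.15.

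At 72 h the transcripts of sperm structure were among the most abundant. Mst84Dd rose from 4.01 ± 2.91 to 7367 ± 595 CPM (log2 11.04, adjusted p = 5.67e-05) and CG31740 from 1.60 ± 2.27 to 6384 ± 705 (11.92). Mst84Db (3309 ± 82.9), Mst77F (2512 ± 22.99), betaTub85D (1649 ± 154) and dj (1639 ± 28.3) were unlisted at 0 h. CycB rose from 25.6 ± 12.9 to 233 ± 39.1 (3.29, adjusted p = 8.15e-05), after a fall at 32 h to 4.80 ± 2.93 (-2.45, adjusted p = 0.0213) whose call was lost without 32 h replicate 2 and with total counts. The Cdc25 gene twe rose from 7.96 ± 6.73 to 47.2 ± 3.21 (2.88). The translation regulator bol rose from 1.01 ± 1.44 to 333 ± 67.4 (7.93), and borr reached 51.8 ± 9.63 from unlisted. eIF4E5 (612 ± 45.4), eIF4E4 (203 ± 11.3), RpL10Aa (93.6 ± 15.6), RpS28-like (89.2 ± 3.87) and RpS28a (27.4 ± 3.37) rose from unlisted, and Cyt-c-d rose from 5.51 ± 1.48 to 635 ± 2.90 (6.86). RpL5 fell from 1006 ± 303 to 335 ± 62.0 (-1.56, adjusted p = 2.65e-04). PCNA (1027 ± 66.1; -1.33) and Mcm7 (39.5 ± 0.155; -1.50) were still below 0 h, the latter not without either 72 h library. Mcm3 rose from 22.5 ± 31.8 to 91.6 ± 5.97 (3.86), a call lost without 0 h replicate 2 or either 72 h library. zpg (14.6 ± 2.87; -1.68) lost its call without 72 h replicate 2. The Mst84D, S-Lap, protamine and RpS28 families hold near-identical copies between which reads may be split, so single members are uncertain.

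Lists at 72 h followed these genes. Spermatid and sperm genes were higher in 35 of 36 (median 8.63, or 7.92 with unlisted values at their highest; camera adjusted p = 5.00e-13, 0.256 with an estimated correlation). Spermatocyte regulators were higher in 10 of 13 with 1 lower (3.29; 0.0326, 0.256 with an estimated correlation). The tMAC genes were higher in 7 of 8 (3.40, or 2.95; 0.0134, 0.262) and testis TAFs in 3 of 4, or 4 adjusted over the list alone (3.75, or 3.30; 0.0378, 0.314). Ribosomal protein genes were lower in 63 of 90 and higher in 3 (mean -0.28, median -0.88 and below 0 under each scaling; 2.85e-15, 0.256 with an estimated correlation), and DNA replication genes lower in 11 of 28 and higher in 3 (-0.59; 3.23e-04, 0.0809). Mitotic division genes had 18 higher and 3 lower of 38 (0.82; 0.767), initiation factors 12 and 9 of 40 (0.761) and translational repressors and mRNP proteins 9 and 2 of 31 (0.776). The counts were 6 and 5 of 29 for mitochondrial respiratory chain genes (0.277), 3 and 1 of 16 for heat shock genes (0.852), 4 and 5 of 25 for piRNA genes (0.118; aub fell from 95.3 ± 32.6 to 28.8 ± 1.84) and 1 and 2 of 23 for early germ cell genes (0.0326, 0.314 with an estimated correlation). Cleavage and polyadenylation genes had 5 higher and 1 lower of 24, with median -0.11 (0.06 with total counts), mean 0.43 and camera adjusted p = 0.236, and the ELAV-related list 5 and 3 of 18, with median -0.36, mean 0.44 and 0.186. Among markers of other cells, accessory gland genes had 0 of 17 past the test (median -2.37; camera adjusted p = 0.0174, 0.671 with an estimated correlation), and fat body genes 1 higher and 4 lower of 15 (-0.67; 0.0162, 0.386). Muscle markers had 2 and 3 of 17 (median -0.28, mean 0.31), cyst cells 3 and 0 of 15, hub 2 and 2 of 7, pigment and terminal epithelium 1 and 1 of 8, and neuron 1 and 0 of 8. The accessory gland sum swung between replicates, from 329 and 2200 CPM at 0 h to 4072 and 2391 at 48 h and 349 and 730 at 72 h. Y-linked fertility genes were not measured in lysate. Genes changed in lysate at 72 h against 0 h numbered 4859 by limma with Benjamini-Hochberg adjustment (3679 higher, 1180 lower), 75.7% of them higher. Total counts without the reads of CG18628 gave 5078 (65.8% higher; median of all genes 0.24 against 0.46). Of the 23 lists, 9 had a camera adjusted p under 0.05, and 3 had without 0 h replicate 2.

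**Figure D1:**
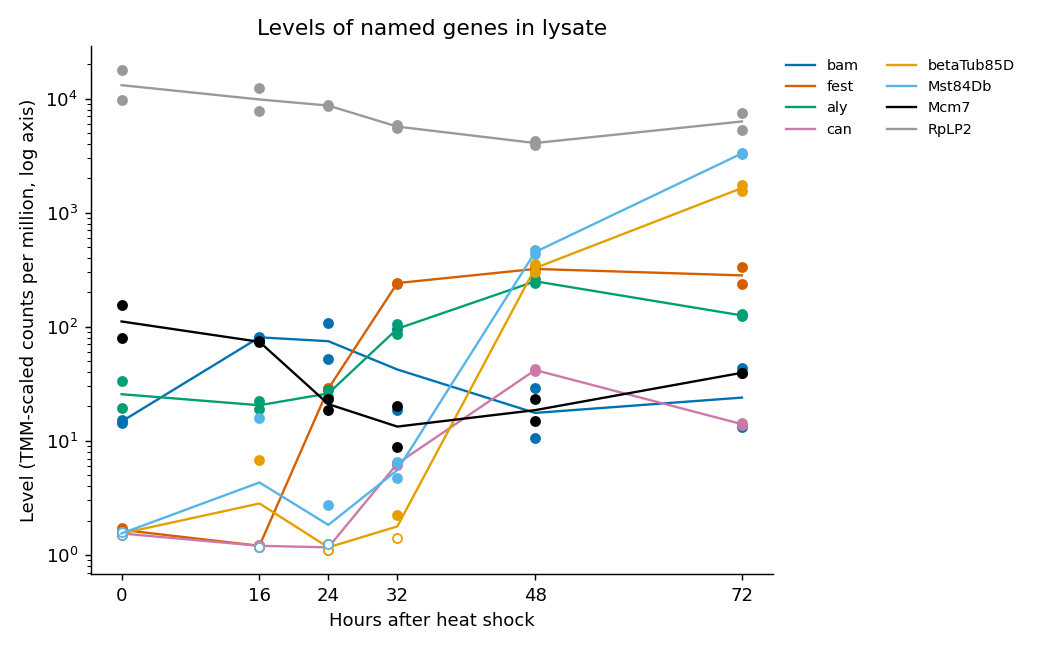
Level of 8 genes in lysate (log axis, scaled CPM) against hours after heat shock, a point per library with lines through the geometric mean and hollow points for unlisted values drawn at the highest level an unlisted gene can have. fest and aly rose by 32 h, betaTub85D and Mst84Db by 48 h, and Mcm7 and RpLP2 fell.

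The deposited positions allowed the choice between the pair of most used 3′ end sites of a gene to be compared. In the percentages below, a site unlisted in a library counted as 0 reads, in lysate and in fractions. A share of 0% or 100% therefore means that a site lay under the listing minimum, not that it was unused. At 16 and 24 h few genes had changed. CG31313 (3R, minus strand, dm6 positions 14566741 and 14566449, both in the 3′ UTR) went from 0% to 80.6% ± 4.49 reads at its proximal site at 16 h (adjusted p = 9.20e-06) and to 77.1% ± 0.657 at 24 h, and CG15210 moved from 17.1% ± 4.52 to 0% at 16 h. The 16 h calls also held Nplp2, and those of both times ACXD, whose sites lie within 100 nt of each other, so that the merging of neighbouring positions in a library could shift reads. Limma with Benjamini-Hochberg adjustment called 4 genes of 3063 at 16 h (2 to proximal, 2 to distal) and 2 of 3063 at 24 h (1 each way), with 220 and 341 at an unadjusted p under 0.05. Joining sites within 100 nt ended the CG31313 call. Without 0 h replicate 2 the counts were 260 and 532, without 16 h replicate 1 or 2 each 8, and without 24 h replicate 1 or 2 they were 7 or 4.

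From 32 h the proximal site gained in many genes. CG3558 (2L, positions 2998390 and 2998729) went from 0% to 84.8% ± 4.29 proximal (adjusted p = 0.00241), CG8677 from 0% to 82.5% ± 4.34 and the tubulin ligase gene TTLL5 from 0% to 73.4% ± 4.10. The fragile X gene Fmr1 (3R, 10102796 and 10101977, 436 and 1255 nt past the stop codon) went the other way, from 71.4% ± 27.3 to 17.9% ± 3.13 (adjusted p = 0.0180), as did NK7.1 (79.3% ± 3.69 to 37.3% ± 10.2). The calls of Fmr1 and NK7.1 were lost without either 32 h library, that of NK7.1 also without 0 h replicate 1, and that of TTLL5 without 32 h replicate 2. Genes with changed site choice in lysate at 32 h against 0 h numbered 296 of 3019 by limma with Benjamini-Hochberg adjustment, 266 to proximal and 30 to distal. The count was 857 without 0 h replicate 2, 147 without 32 h replicate 1 and 59 without 32 h replicate 2, and 5 with only the libraries of the groups compared.

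At 48 h the proximal site gained in further genes. orb, which encodes an RNA-binding translation regulator, went from 1.98% ± 2.80 to 87.8% ± 3.27 proximal (adjusted p = 1.16e-05) and the transcription factor gene chinmo (2L, 1697394 and 1704952, the latter in cpb) from 0% to 89.3% ± 3.08, a call lost when the outermost sites were paired. The lipid kinase subunit gene Vps15 went from 100% to 13.7% ± 2.10 and Fmr1 to 13.8% ± 2.05. Genes with changed site choice in lysate at 48 h against 0 h numbered 970 of 3046 by limma with Benjamini-Hochberg adjustment, 860 to proximal and 110 to distal. The count was 491 with only the libraries of the groups compared, and 401 with pairs in the 3′ UTR, chosen after the data were seen.

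At 72 h the same kinds of switch were near complete in the listed reads of single genes. CG3982 (3L, minus strand, 9415755 in the 3′ UTR and 9415357 downstream of the annotated end) went from 0% to 98.9% ± 0.603 proximal (adjusted p = 1.99e-05). The gene m-cup (3R, 17145452 and 17144742) went from 0% to 95.2% ± 0.654 and orb (3R, 23265654 and 23264647, 199 and 1206 nt past the stop codon) to 92.5% ± 1.70 (adjusted p = 5.16e-06). Toward the distal site, Vps15 (3R, 9240757 and 9240495) went from 100% to 5.82% ± 0.450 proximal, the succinyl-CoA ligase gene ScsbetaA (3R, 8942130 and 8942770) from 99.1% ± 1.32 to 11.3% ± 0.197 (adjusted p = 5.16e-06). Dok (X, 7328735 and 7329125, the latter in Acsf3) went from 100% to 16.6% ± 1.83, Ltn1 to 16.7% ± 1.29 and pll to 27.6% ± 0.130. Genes with changed site choice in lysate at 72 h against 0 h numbered 737 of 3026 by limma with Benjamini-Hochberg adjustment, 651 to proximal and 86 to distal. That count was 1175 without 0 h replicate 2 and 467 without 72 h replicate 2, 408 with only the libraries of the groups compared, and 288 with pairs in the 3′ UTR. In the 651 genes the median proximal share went from 6.96% to 61.9%, and the median sites lay 166 and 487 nt past the stop codon. Reads of the proximal site were higher in 642 of them and reads of the distal site lower in 523. The choice of these genes by a rise of the proximal share favours both. In the 2289 genes not called the counts were 886 and 1524. Of the 651, 265 had both sites in an annotated 3′ UTR and 234 had an unlisted proximal site at 0 h. In the 86 genes the share went from 95.3% to 40.9%, with sites at 129.5 and 354.5 nt. Of the 86, 36 had both sites in an annotated 3′ UTR and 39 a distal site downstream of the annotated gene end. Such a distal site was also found in 356 of the 651 and in 1109 of the 2289 genes not called. Of the 2289, 1051 had both sites in an annotated 3′ UTR. A site lay in another gene in 21 of the 86, in 25 of the 651 and in 142 of the 2289.

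**Figure D2:**
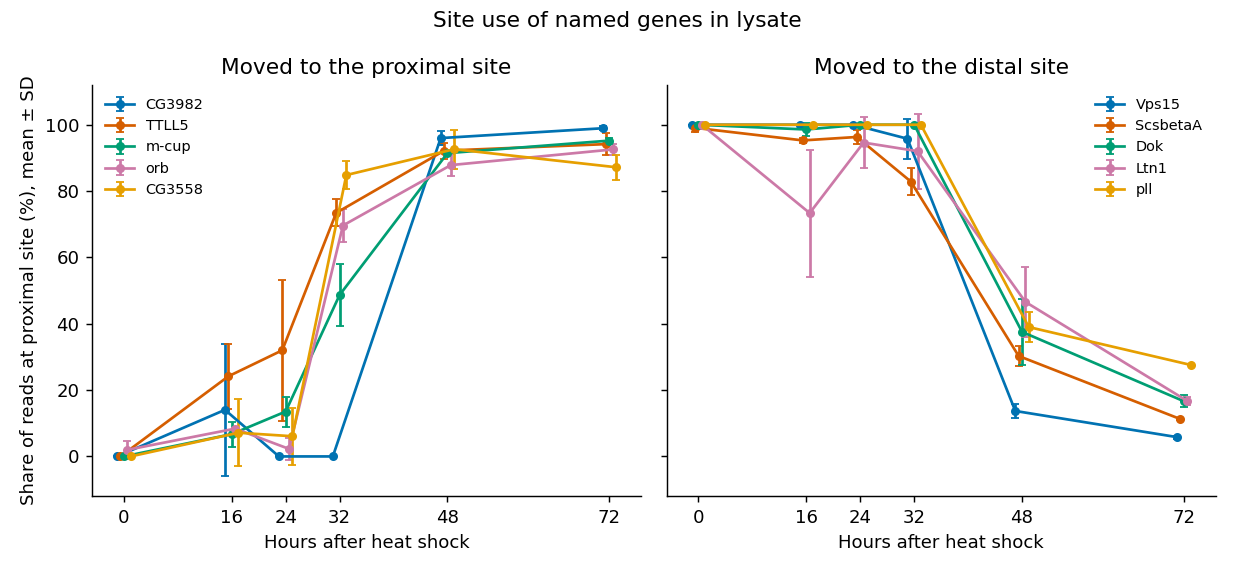
Share of reads at the proximal site (percent, mean ± SD, n = 2) against hours after heat shock for 5 genes that moved to the proximal and 5 that moved to the distal site at 72 h. CG3982 ended at 98.9% and Vps15 at 5.82%.

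Over 2887 genes with both sites, the median proximal share per library was 40.1% ± 6.14 at 0 h, 35.98% ± 1.43 at 16 h, 37.2% ± 0.117 at 24 h, 46.5% ± 1.49 at 32 h, 57.2% ± 0.992 at 48 h and 53.4% ± 1.83 at 72 h. Across the 12 libraries it correlated with time (Spearman rho = 0.834, two-sided permutation p = 0.0015, 0.003 after Benjamini-Hochberg adjustment over the family of 2; Pearson r = 0.781, permutation p = 0.00302). Without both 72 h libraries r was 0.766.

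**Figure D3:**
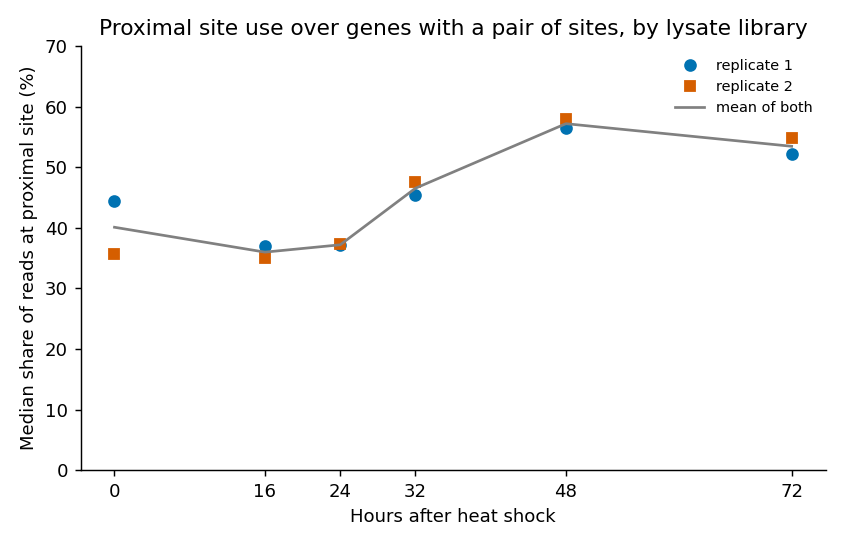
Median share of reads at the proximal site (percent) over 2887 genes in each of the 12 lysate libraries, against hours after heat shock. Both 48 h libraries lay above every library of 0 to 32 h.

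Comparing the 4+ ribosome pool with free RNA asks which transcripts carried many ribosomes. At 24 h the gene of the ribosomal stalk protein RpLP1 stood at 35367 ± 4825 CPM in free and 1371 ± 75.6 in 4+ RNA (log2 -4.68, adjusted p = 1.65e-06). Muscle transcripts were also poor in 4+, with Mhc at 235 ± 29.6 and 25.8 ± 8.20 (-3.21, adjusted p = 2.43e-04) and Mlc2 at 787 ± 171 and 37.9 ± 0.403 (-4.36), and so was the accessory gland gene Mst57Db (243 ± 64.3 and 5.21 ± 7.37). The cleavage factor gene Cpsf73 was richer in 4+ (10.7 ± 5.03 and 82.0 ± 35.04; 2.91, adjusted p = 0.00811), as was pira (14.0 ± 3.46 and 150 ± 0.866; 3.45). Muscle markers were lower in 11 of 17 (16 adjusted over the list alone; median -2.32; camera adjusted p = 8.80e-15, 0.0194 with an estimated correlation) and ribosomal protein genes in 31 of 93 (51, with 1 higher, adjusted over the list alone; -1.67; 2.81e-17, 0.480 with an estimated correlation). Accessory gland markers were lower in 4 of 17 (camera adjusted p = 3.26e-04, 0.480 with an estimated correlation) and 3 cleavage genes higher with 1 lower of 25 (0.0331, 0.480). Genes enriched in 4+ ribosomes against free at 24 h, or depleted there, numbered 626 of 10777 by limma with Benjamini-Hochberg adjustment (139 higher in 4+, 487 lower; median of all genes -0.44, or -0.05 over the 7922 listed in a compared pool). The count was 220 without free replicate 1, 185 without free replicate 2, 241 without 4+ replicate 1 and 1702 without replicate 2 of the 72 h 60S pool. The Cpsf73 call was lost without 4+ replicate 1 or free replicate 2, that of pira without free replicate 1 and that of Mst57Db without 4+ replicate 2. Set against 80S RNA, 349 genes passed, with Mhc, Cpsf73, pira and Mst57Db no longer among them.

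At 48 h spermatid transcripts were among those poor in 4+. Mst77F stood at 210 ± 170 CPM in free and 13.6 ± 8.91 in 4+ RNA (log2 -3.83, adjusted p = 0.0130) and Mst84Dd at 2051 ± 2112 and 37.0 ± 19.8 (-5.36, adjusted p = 0.00205). RpLP1 (26361 ± 2353 and 832 ± 3.93; -4.98), Mhc (186 ± 54.5 and 9.82 ± 2.84; -4.23) and Mlc2 (643 ± 323 and 20.8 ± 3.52; -4.86) were lower too. In contrast fest (1382 ± 403 and 5179 ± 23.2; 1.94, adjusted p = 0.00817), aly (99.3 ± 4.49 and 392 ± 81.3; 1.97) and HP5 (3.10 ± 0.115 and 42.6 ± 3.12; 3.72) were richer in 4+. Muscle markers were lower in 16 of 17 (camera adjusted p = 9.66e-16, 0.0139 with an estimated correlation), ribosomal protein genes in 41 of 93, or 51 adjusted over the list alone (-1.85; 8.94e-18, 0.327), and spermatid genes in 11 of 36, or 16 with 1 higher over the list alone (-1.96; 4.58e-07, 0.430). The 11 spermatid genes listed at 24 h had a median of -2.14 there, with 2 lower (camera adjusted p = 0.170). The piRNA (median 0.96; 0.00560, 0.0479 with an estimated correlation) and DNA replication lists (0.65; 0.00690, 0.0479) were higher as sets with 1 member past the test each way and 1 higher, and 3 of 8 tMAC genes were higher (0.0203, 0.494). Genes enriched in 4+ ribosomes against free at 48 h, or depleted there, numbered 1170 by limma with Benjamini-Hochberg adjustment (232 higher, 938 lower). Without free replicate 1, 4+ replicate 1 or 4+ replicate 2 the counts were 346, 597 and 495, and 2326 without replicate 2 of the 72 h 60S pool. The calls of Mst77F, Mst84Dd, fest and aly were lost without free replicate 1, those of Mst77F and fest also without 4+ replicate 2, and that of aly without 4+ replicate 1 or free replicate 2. Against 80S RNA 283 genes passed, without these 4, Mhc or HP5.

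By 72 h the depletion of spermatid transcripts from 4+ was broad. Mst84Dd stood at 29415 ± 9401 CPM in free and 238 ± 28.5 in 4+ RNA (log2 -6.91, adjusted p = 3.14e-05). The protamine genes ProtA stood at 587 ± 230 and 16.5 ± 1.93 (-5.09) and ProtB at 260 ± 26.1 and 7.18 ± 2.63 (-5.19, adjusted p = 2.39e-06), and Mst77F at 1959 ± 244 and 100.3 ± 6.4996 (-4.28). The cap-binding gene eIF4E5 (701 ± 184 and 20.9 ± 6.74; -5.06) was depleted alike. In contrast fest (1328 ± 241 and 4531 ± 1502; 1.74), aly (87.2 ± 16.1 and 348 ± 60.5; 2.00) and can (3.73 ± 0.800 and 43.0 ± 13.1), genes of the spermatocyte programme, were richer in 4+. So were transcripts of the piRNA and DNA replication lists, with nxf2 at 2.69 ± 0.425 and 19.2 ± 2.24 (2.79), tapas at 31.5 ± 6.47 and 116 ± 19.2 (1.89) and RnrL at 6.41 ± 0.628 and 69.7 ± 12.97 (3.41, adjusted p = 7.08e-04), and vas reached 9.16 ± 2.77 in 4+ from unlisted. The replication licensing gene dup was poor in 4+ (131 ± 15.6 and 20.4 ± 1.41; -2.68). The cleavage genes Cpsf73 (12.05 ± 6.58 and 89.9 ± 3.72; 2.97) and Wdr33 (2.84) were richer in 4+, the latter turning to -0.03 against 80S RNA.

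Spermatid genes at 72 h were lower in 23 of 36, or 24 adjusted over the list alone (median -2.50, below 0 under each scaling; camera adjusted p = 4.84e-07, 0.352 with an estimated correlation). Ribosomal protein genes were lower in 31 of 93, or 34 with 2 higher over the list alone (-1.21; 3.71e-05, 0.560), and muscle markers in 8 of 17 with 1 higher, or 11 and 1 over the list alone (-2.07; 0.00147, 0.352). The 4+ ratio rose with coding length (Spearman rho = 0.458 over genes outside the spermatid list), and the 1939 genes with the shortest coding regions (median 399 nt) had a median of -2.20. With that trend taken off, a check chosen for these lists after the data were seen, ribosomal protein genes lay at 0.43, within the -0.39 to 0.56 of random lists of like length. The same check gave them -1.01 at 24 h (random -0.29 to 0.32) and -0.75 at 48 h (-0.30 to 0.42), and muscle markers -1.64 at 72 h (-0.83 to 0.995). Of the lists higher below, mitotic division genes lay within random lists at 72 h (0.18, -0.49 to 0.54), and the piRNA (1.14), DNA replication (1.07), cleavage (1.07), heat shock (1.45) and spermatocyte regulator lists (1.13) above them. At 24 h, of these lists, only mitotic division genes lay above random lists (0.67, -0.38 to 0.49). At 48 h they did so again (0.48, -0.37 to 0.45), as did piRNA (0.84) and DNA replication genes (0.54). Cleavage (0.50), heat shock (0.45) and spermatocyte regulator lists (0.40) lay within at 48 h. The piRNA list was higher in 7 of 26 (1.42; 5.62e-04, 0.0203 with an estimated correlation) and DNA replication genes in 5 of 28 with 1 lower, or 3 and 1 over the list alone (1.23; 0.00134, 0.0306). Cleavage genes were higher in 6 of 25 with 1 lower (0.00147, 0.318), heat shock genes in 5 of 16 (0.00147, 0.352), spermatocyte regulators in 5 of 13 (0.0396, 0.398), and mitotic division genes in 6 of 37 with 1 lower (0.00883, 0.352). Higher and lower counts were 3 and 0 of 20 for the ELAV-related list, 5 and 1 of 31 for repressors, 5 and 4 of 40 for initiation factors, 7 and 6 of 30 for mitochondrial genes, 3 and 0 of 15 for cyst cells, and 2 and 1 for tMAC and testis TAFs (both higher). After the length trend the ELAV-related list (0.61), repressors (0.42), tMAC (0.73), testis TAFs (0.89) and cyst cells (0.57) lay within random lists. Initiation factors (0.87) and mitochondrial genes (0.96) lay above them. None of 4 Y-linked genes passed (0.744). Genes enriched in 4+ ribosomes against free at 72 h, or depleted there, numbered 2861 of 10777 by limma with Benjamini-Hochberg adjustment (881 higher, 1980 lower). This fell to 1493 without free replicate 1, 1752 without 4+ replicate 1 and 1858 without 4+ replicate 2. The calls of fest, aly, nxf2, tapas, vas and Wdr33 were lost without free replicate 1, those of nxf2 and vas also without any other of the 4 libraries, those of aly and tapas without 4+ replicate 1 and that of fest without 4+ replicate 2. Set against 80S RNA 659 genes passed, and none of the genes named above for 72 h kept its call.

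Genes enriched in 4+ ribosomes against free at 24 h were few relative to those depleted, but this split depended on scaling. The share of calls higher in 4+ was 22.2% at 24 h and 76.5% with total counts (1491 genes). Genes enriched in 4+ ribosomes against free at 48 h made up 19.8% of the calls, and 74.3% with total counts (2383 genes). Genes enriched in 4+ ribosomes against free at 72 h made up 30.8%, and 65.1% with total counts (4269 genes). That scaling moved the median of all genes to 0.23, 0.63 and 0.69. Relative log expression factors gave 39.4% at 24 h and a median of -0.23, with 29.3% at 48 h. No gene named above changed direction under a scaling, and the medians of spermatid genes at 72 h ran from -1.66 to -2.72 and those of ribosomal protein genes from -0.38 to -1.43.

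**Figure D4:**
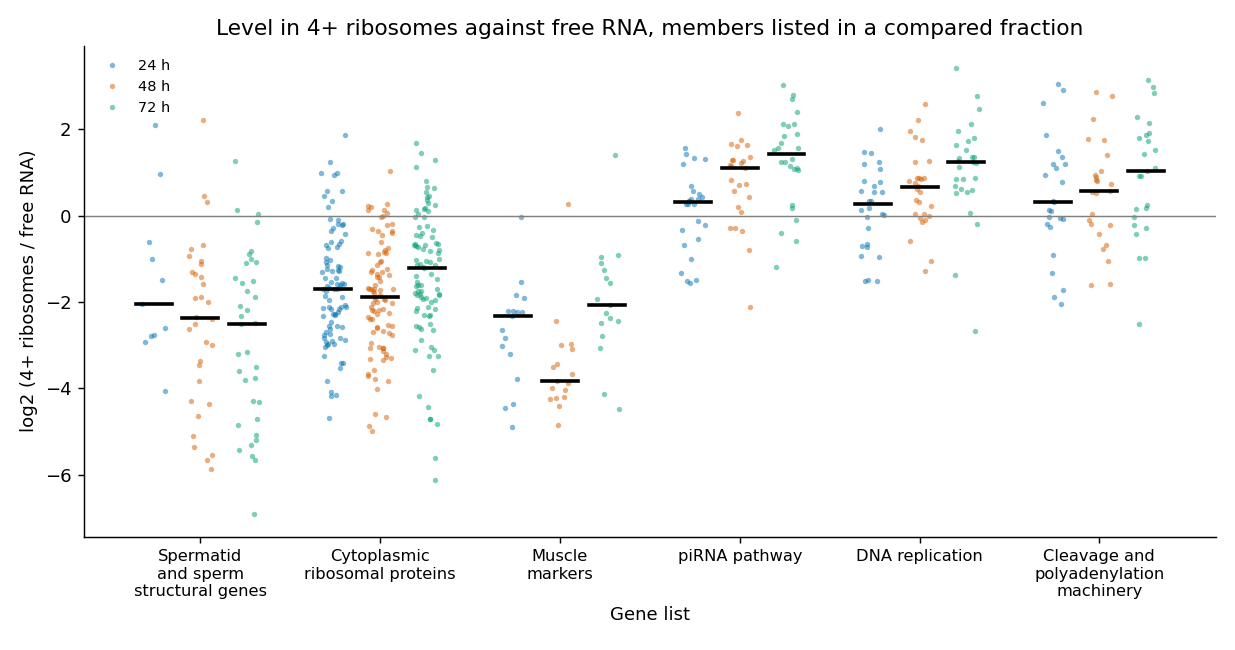
Log2 ratio of 4+ to free RNA for members of 6 gene lists at 24, 48 and 72 h, a point per gene listed in a compared pool, with bars at the medians. The medians of spermatid genes at 72 h and of muscle markers at each time lie below 0 under each scaling.

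Whether the 4+ to free ratio itself changed from 24 to 72 h was tested as an interaction. The transport regulator gene Rab3-GAP went from 37.6 ± 2.20 CPM in free and 34.5 ± 19.2 in 4+ RNA at 24 h to 2344 ± 720 and 95.5 ± 30.8 at 72 h (log2 -4.36, adjusted p = 0.0203 over listed genes), and CG32161 from 1.13 ± 1.60 and 42.0 ± 24.5 to 474 ± 218 and 51.1 ± 8.64 (-7.89, adjusted p = 0.0203). The snoRNP gene Gar1 gained, from 207 ± 25.6 and 57.5 ± 13.0 to 51.1 ± 15.5 and 154 ± 7.76 (3.52, adjusted p = 0.0237), as did CG3526 (230 ± 39.1 and 61.6 ± 17.3 to 294 ± 22.2 and 770 ± 151; 3.33). Genes whose 4+ against free enrichment changed from 24 h to 72 h numbered 690 of 10777 by limma with Benjamini-Hochberg adjustment (71 higher, 619 lower). For 579 of them neither pool had the gene listed in both libraries at 1 or both of the times, so that fill values entered each side of the ratio. Among the 7470 genes listed in both libraries of a pool at each time, 111 of those calls remained (54 higher, 57 lower). A refit to these genes alone called 18 (4 higher, 14 lower), with 915 at an unadjusted p under 0.05. The 690 became 274 without 24 h free replicate 1, 447 without 24 h 4+ replicate 1, 229 without 72 h free replicate 1, 266 and 371 without 72 h 4+ replicate 1 or 2, and 1547 without 72 h 60S replicate 2. Rab3-GAP, Gar1, CG3526 and CG32161 were not called when 4+ was set against 80S. The distal site of CG32161 lies in Zcchc7, and its proximal share differed by -80.1 percentage points in 4+ against free RNA at 72 h. Reads of Zcchc7 may therefore enter the level given for CG32161, so its change in ratio need not be one of a single gene.

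Site choice in 4+ against free RNA asks whether the forms of a gene differ in ribosome loading. At 24 h the ceramide synthase gene schlank (X, 6258159 and 6257662) had 11.8% ± 0.640 proximal reads in free and 82.0% ± 10.9 in 4+ RNA (adjusted p = 1.04e-04). Hsp27 (3L, 9384833 and 9385281) had 2.58% ± 0.598 and 85.3% ± 0.203 (adjusted p = 0.0181), and the kinase gene Pkc98E 88.7% ± 1.39 and 22.1% ± 0.756. At 48 h fbp had 20.1% ± 7.499 and 100%, and CG42566 90.3% ± 4.34 and 17.0% ± 8.95. At 72 h dup (2R, 15376611 and 15376231) had 8.45% ± 4.61 and 97.1% ± 4.04 (adjusted p = 7.76e-04). CG32161 (3L, 16847001 and 16847371, the latter in Zcchc7) had 99.1% ± 0.284 and 19.0% ± 1.86 (adjusted p = 4.46e-07) and SkpB (2R, 12139390 and 12139274) 100% and 10.4% ± 0.213. Genes whose sites differ between 4+ ribosomes and free at 24 h numbered 161 of 3350 by limma with Benjamini-Hochberg adjustment (136 more proximal in 4+, 25 more distal), 67 of 3351 at 48 h (50 and 17) and 156 of 3643 at 72 h (51 and 105). The difference changed from 24 to 72 h in 10 of 2770 genes, all toward distal. The Hsp27 call was lost without any 1 of the 4 libraries and that of Pkc98E without either free library. Counts moved to 38, 24 and 81 at 24 h without free replicate 1, free replicate 2 or 4+ replicate 1. At 48 h they moved to 10, 36, 22 and 19 without free replicate 1 or 2 or 4+ replicate 1 or 2, and at 72 h to 19, 99, 26 and 42. Against 80S RNA 13, 1 and 15 genes passed, none of those named here among them, and SkpB turned to 2.24 percentage points.

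The lysate switches were also looked for in the fractions, which are separate libraries. From 24 to 72 h, averaged over the 6 pools, CG3982 gained 91.5 percentage points of proximal reads (adjusted p = 5.25e-14), Cds gained 92.8 (adjusted p = 2.03e-13), and Vps15 changed by -95.9 (adjusted p = 2.41e-15) and Dok by -70.4. Genes with changed site choice in fractions at 72 h against 24 h numbered 1125 of 2419 by limma with Benjamini-Hochberg adjustment, 1013 of them to proximal, and 191 without 72 h 60S replicate 1. With the pools of a time and replicate number summed, chosen after the data were seen, 1257 passed. Of 454 genes that had moved to proximal in lysate, 445 (98.0%) did so here, 392 with a call and 0 called distal. Of 61 that had moved to distal, 46 did so, 29 with a call, and 6 were called proximal. Genes not called in lysate also moved to proximal in 994 of 1300 cases (76.5%), 413 with a call.

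At 72 h the forms of the switch genes differed between pools. In 564 genes that had moved to the proximal site in lysate, the median log2 odds of proximal reads in 4+ against free was -1.02, with 37 called lower and 1 higher. In 73 genes that had moved to the distal site it was 0.88 (7 higher, 2 lower), and in 1627 genes not called it was 0.00. Both classes differed from the uncalled genes (permutation p = 0.0001 across genes, the smallest that 10000 resamples can give, 1.67e-04 after Benjamini-Hochberg adjustment), although genes are not independent replicates. At 24 h the medians were 0.32, 0.66 and 0.63 and at 48 h 0.14, 0.53 and 0.54, and those moving to proximal already differed from the uncalled genes (adjusted p = 0.00337 and 1.67e-04 by permutation across genes). The medians of the change per gene from 24 to 72 h were -1.38 (493 genes), 0.25 (64) and -0.60 (1525) (permutation p = 0.0001 and 0.0005 for the switch classes). At the level of whole genes the 4+ to free ratio did not pass as a set from 24 to 72 h, with camera adjusted p = 0.744 for the 642 genes that moved to proximal (median 0.13 against 0.12 for all genes) and 0.770 for the 85 that moved to distal (-0.05). Over genes listed in a compared pool alone, a restriction chosen after the data were seen, both classes stood lower than other genes ("Ribosome loading of switch genes from 24 h to 72 h", adjusted p = 0.0234, 0.585 with an estimated correlation). For genes that moved to proximal this was the opposite direction. Against 80S the value of "Ribosome loading of switch genes from 24 h to 72 h, genes that moved to the distal site" was 0.0483.

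**Figure D5:**
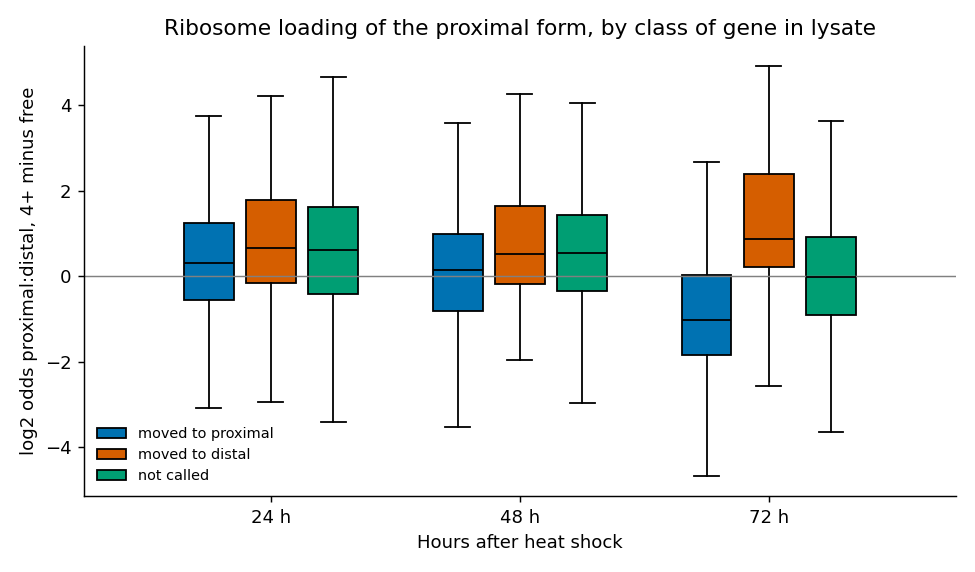
Log2 odds of proximal reads in 4+ against free RNA (boxes span the quartiles, whiskers without outlying points) for genes that moved to the proximal site in lysate, to the distal site, or were not called, at 24, 48 and 72 h. At 72 h the medians were -1.02, 0.88 and 0.00.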

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

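The ratio of 4+ to free RNA changed from 24 to 72 h for 690 genes, and the site difference between these pools for 10. As sets, without single members past the test, that ratio was higher for piRNA pathway (median log2 1.35, camera adjusted p = 0.00570; 0 of 26), heat shock (1.57, 0.00570; 0 of 16), DNA replication (1.11, 0.0178; 0 of 28), accessory gland (1.65, 0.0178; 0 of 17) and early germ cell genes (0.47, or 0.07 with relative log expression factors, 0.0427; 0 of 23). Initiation factors were higher as a set with 1 member each way of 40 (0.58, or 0.15 with those factors, 0.0389), and spermatid genes lower with 5 of 36 (-1.55, 6.72e-05). Those factors turned the median of all genes from 0.12 to -0.31. With an estimated correlation none passed (adjusted p = 0.0768, 0.492, 0.157, 0.492, 0.492, 0.513 and 0.492 in that order), and over genes listed in a pool at both times spermatid, heat shock and piRNA genes had camera adjusted p of 0.0112, 0.0186 and 0.0478. DNA replication (0.145), early germ cell (0.171), initiation factor (0.182) and accessory gland genes (0.369) did not pass there. In 579 of the 690 neither pool had the gene listed in both libraries at 1 or both of the times, so that fill values entered each side of the ratio. Entries naming several genes were not analysed and held at most 0.0428% of a library's reads.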

How the results depend on the processing

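Counts of calls depended on the spread estimated from few libraries, and the cause of each shift was not tested. The results varied were "Genes changed in lysate at 16 h against 0 h", "Genes changed in lysate at 24 h against 0 h", "Genes changed in lysate at 32 h against 0 h", "Genes changed in lysate at 48 h against 0 h" and "Genes changed in lysate at 72 h against 0 h", "Genes enriched in 4+ ribosomes against free at 24 h", "Genes enriched in 4+ ribosomes against free at 48 h" and "Genes enriched in 4+ ribosomes against free at 72 h", and "Genes whose 4+ against free enrichment changed from 24 h to 72 h" (below, the interaction). For sites they were "Genes with changed site choice in lysate at 16 h against 0 h", "Genes with changed site choice in lysate at 24 h against 0 h", "Genes with changed site choice in lysate at 32 h against 0 h", "Genes with changed site choice in lysate at 48 h against 0 h" and "Genes with changed site choice in lysate at 72 h against 0 h", "Genes whose sites differ between 4+ ribosomes and free at 24 h", "Genes whose sites differ between 4+ ribosomes and free at 48 h" and "Genes whose sites differ between 4+ ribosomes and free at 72 h", "Genes with changed site choice in fractions at 72 h against 24 h", and "Ribosome loading of switch genes from 24 h to 72 h". Total counts gave 330, 501 and 2512 genes at 16, 24 and 32 h, and 1491 and 2383 in 4+ at 24 and 48 h. Using the replicate number as a replicate block gave 48 and 105 genes at 16 and 24 h and changed no other result as far. Same-numbered lysate libraries deviated together in 3 of 15 pairs of groups, and fraction libraries in 1, 10 and 7 of 15 at 24, 48 and 72 h. As not every pair did, the numbers were not taken to pair the samples, but pools of a gradient may share deviations at 48 and 72 h, which the 4+ against free tests and the site tests in fractions treat as independent. With only the libraries of the groups compared, 0, 0, 94 and 2730 genes passed at 16 to 48 h, 1612, 1959 and 5403 in 4+ and 1741 for the interaction, and for sites 1, 5, 491 and 408 at 24 to 72 h and 55 and 353 in 4+ at 24 and 72 h. Setting 4+ against 80S left 349, 283 and 659 genes, 25 for the interaction, and 13, 1 and 15 for sites. Against the mean of free, 40S, 60S and 80S there were 1159 genes at 24 h, 294 for the interaction and 85, 28 and 14 for sites. The mean of 2-3 and 4+ against that of free and 40S gave 2063 genes at 48 h and 245, 113 and 291 for sites. A minimum of 20 percentage points gave 2 at 16 h and 543 in fractions, joining within 25 nt 7 and 6 at 16 and 24 h, and joining within 100 nt 1 and 1. With an estimated correlation 0 lists passed in lysate at 72 h and 2 in 4+ against free. Of the settings chosen after seeing the data, total counts without CG18628 gave 1466, 2186 and 4325 genes in 4+. Leaving out all 60S libraries gave 2034, 2676 and 4554, 1734 for the interaction, and 268 and 116 for sites at 24 and 48 h. Limma-trend gave 345 and listed genes alone 18 for the interaction. Pairs over 100 nt apart gave 2 and 1 at 16 and 24 h, and pairs in the 3′ UTR 2, 1, 136, 401 and 288 in lysate, 81, 24 and 59 in 4+ and 470 in fractions. Unlisted sites at 0 plus 0.5 gave 7 and 5 at 16 and 24 h and 53, 26 and 49 in 4+, and at the highest unlisted count 265 in 4+ at 72 h. An F test over all sites called 69, 172, 1062, 2673 and 2271 in lysate, 723, 375 and 672 in 4+ and 4158 in fractions. DESeq2, diffSpliceDGE of edgeR and poly(A) signal windows were not run.

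Leaving out 1 library, with the lone sample assumed to vary like the other groups, moved gene counts to 25 to 1780 at 16 h, 21 to 2483 at 24 h, 397 to 3335 at 32 h, 3516 to 5775 at 48 h and 3617 to 6018 at 72 h, and in 4+ to 185 to 1702, 346 to 2326 and 1493 to 4197, with 229 to 1547 for the interaction. For sites the ranges were 6 to 260, 2 to 532, 59 to 857, 686 to 1378 and 467 to 1175 in lysate, 24 to 194, 10 to 93 and 19 to 170 in 4+ and 191 to 1132 in fractions. Lists numbered 3 to 9 in lysate and 10 to 14 in 4+.

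Of 202 list medians 63 turned under at least 1 other scaling (54 with total counts), as did 7 of 9 medians of all genes. Directions of single genes turned in few cases. bam was at -0.48 at 48 h and -0.16 at 72 h without replicate 2 of that time, and at 0.99 and 1.55 without replicate 1. Against 80S, CG9098 (-0.83), CG42724 (-0.12), CG34168 (0.40) and CG31740 (0.83) turned at 48 h, "Wdr33, level, Genes enriched in 4+ ribosomes against free at 72 h" (-0.0274) and CG15579 (1.07) in the interaction. For sites in percentage points, those turned were "ago, proximal share, Genes whose sites differ between 4+ ribosomes and free at 24 h" (-0.478), CG1316 (11.5) at 24 h, "Hsp27, proximal share, Genes whose sites differ between 4+ ribosomes and free at 48 h" (-2.51), CG6959 (-4.77), "pigs, proximal share, Genes whose sites differ between 4+ ribosomes and free at 48 h" (-12.3), "noc, proximal share, Genes whose sites differ between 4+ ribosomes and free at 48 h" (-8.65) and chinmo (4.95) at 48 h, and fbp (0) and SkpB (2.24) at 72 h. With the most proximal and most distal site, "sm, proximal share, Genes with changed site choice in lysate at 32 h against 0 h" (45.6) turned, Nrx-IV (10.4) and CG7220 (16.1) at 48 h and Nrx-IV (10.4) at 72 h. For "Ribosome loading of switch genes from 24 h to 72 h", a test of whole-gene levels, the median turned against 80S (camera adjusted p = 0.233), with 0.0483 for "Ribosome loading of switch genes from 24 h to 72 h, genes that moved to the distal site". Over listed genes alone both were 0.0234, lower than other genes and for the former the opposite direction, 0.585 with an estimated correlation, and over all genes both were 0.920 with it. Leaving out 1 library gave 0.241 to 0.816 and 0.423 to 0.933, the latter turning at 0.816 without replicate 2 of 72 h 4+.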

Other observations

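The tests on listed genes at both times, on genes that moved to the distal site, on pairs over 100 nt apart and on splits of whole replicates were chosen after the results were seen, and the others before. Spermatid genes were poor in 4+ RNA at 72 h (median log2 -2.50). Short coding regions could hold few ribosomes, and the 1939 genes with the shortest coding regions (median 399 nt) had a median of -2.20, but after the coding-length trend the list still lay at -2.19, outside the -0.564 to 0.664 of random lists of 36. A depletion already present at 24 h could also account for it. The 11 members listed then had a median of -2.05 in the fit to all genes, beside the -2.14 given above. After the coding-length trend they lay at -0.985 at 24 h, below the -0.927 to 0.735 of random lists. In the 11 listed at both times the ratio changed by a further -1.66 (-0.524 to 0.893 in random lists), but only 3 members were listed in both pools at both times. S-Lap2, gdl, janB and sowah, listed in both pools at 24 h, changed by -1.89, -1.66, -1.01 and -0.92. The others of the 11 took a fill value in at least 1 library at 24 h, which for most limits how low the ratio can go. With so few members of the list measured in both pools, this stays open. Delayed translation of these transcripts may be the cause, which was not tested, and against 80S RNA no spermatid gene named in the report kept its call.

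In genes that moved to the proximal site, the proximal form was poorer in 4+ at 72 h (median log2 odds -1.02). A fixed lower loading of shorter 3′ UTRs might give this, but genes that moved to the distal site had 0.883 (0.569 to 1.496, n = 73). In 21 of the 86 genes of that class a site lay in another gene, whose reads may enter this value. Few reads could also matter, yet the genes with more reads had -1.08 (-1.27 to -0.819, n = 282). Both intervals come from resampling genes, which are not independent replicates. They leave out the spread between the 2 libraries of a pool, so on their own they exclude neither explanation. RNA of cells at earlier stages, with the earlier site choice, may make up more of the 4+ pool, and this remains possible, as the lysate move correlated with the loading difference across genes (Spearman rho = -0.201, permutation p = 0.0001, n = 564). Regulated translation of the new form stays open and was not tested.

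Most site calls at 72 h went to the proximal site. Merging of sites within 50 nt could move listed positions, but 90.4% of 633 calls among pairs over 100 nt apart went that way. The listing minimum could hide the proximal site at 0 h, but 90.0% of 289 calls with both sites listed in the 4 libraries did so. In fractions 1 split of 100 of the libraries, the real one with 1125 calls, reached that count and the highest other split had 722, which excludes chance only if the pools are independent. If the pools of a replicate number came from a shared gradient, which the labels leave open, 3 splits remain, too few for a share under 0.05, and the highest other had 0 calls. A change of cell types in the testis may shift site use as well as a change within cells, and the 90.4% does not separate them.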
